A study of Homo sapiens with 24 samples.

How the data were processed

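RNA was measured by sequencing in 24 libraries of MDA-MB-231: 4 lines (control, WT, dSAP and dSRF MRTF-A) in 2 cultures, with 3 replicates each. RNA was extracted with a column kit and libraries were made from total RNA with ribosomal RNA depletion, per the labels' protocols, although the molecule field of the labels says polyA RNA. Reads were assigned to transcripts with Salmon (version 11.3 as written) on hg38 after quality control with FastQC, per the submitters' processing notes. The gene annotation is not given in the sources used here. The deposited tables hold estimated counts and TPM per gene, with 37247 gene ids in each. The deposited expected counts are not whole numbers and were rounded. Gene ids were matched to symbols and positions with GENCODE 29: 34436 had a symbol and 34620 a position.

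Groups were taken from the titles. The genotype field disagrees with the titles for 16 of 24 libraries. Groups from that field were run as an alternative, and the level of MRTFA in each library was used as a check. The rounded counts were fitted with edgeR 4.0.16 in R 4.3.3: genes were kept with filterByExpr, libraries scaled with TMM (factors 0.890 to 1.09), and 1 quasi-likelihood model with 8 groups (robust, 16 residual degrees of freedom) was fitted to all libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 14986 genes tested, of which 1012 had no symbol. The comparisons were each line against control, each mutant against WT and the mutants against each other within a culture, control in 3D against 2D, and the difference of each line's effect between cultures, 16 in all. CPM levels are TMM-normalised.

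Total counts per library ran from 13968829 to 23023415 (median 18155000), and the common biological coefficient of variation was 13.1%. Mitochondrial genome genes held 0.398% to 1.45% of counts, replication-dependent histone genes 0.0250% to 0.240% and ribosomal protein genes 0.768% to 1.34%. MRTFA held up to 1.12%. On simulated data (libraries with known changes added), 78 of 100 genes changed by 2-fold were recovered in 2D WT against control with 5 false calls of 138, and 85 of 100 in 3D dSRF against control with 3 of 156.

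Gene lists on themes of MRTF and SRF biology, cell state, metabolism, RNA quality and other cell types were fixed before the data were examined. Of 31 lists, 30 had at least 3 tested members and were tested with camera (limma 3.58.1) on log2 CPM with prior count 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 480 tests. 165 were called, 14 of them also with an estimated correlation. Named genes were drawn, not exhaustively, from sets defined by a rule: among called genes with at least 1 CPM in a group, non-overlapping replicates and an assigned symbol, the 8 largest rises and 8 largest falls against control and for control in 3D against 2D, the 5 and 5 largest in other comparisons, 12 genes fixed beforehand (1 of them, and 3 list members, are not reported here), and up to 4 members with the lowest p of each list described, with MYL7 in dSAP against WT added after seeing the data. Folds against a group at 0 counts are lower bounds against a floor of 3 counts over the group. With 1 to 3 counts, levels are given. Genes in near-identical families or in the MHC region of chromosome 6 (28000000 to 34000000, GRCh38) are reported as uncertain.

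The alternatives were RLE size factors, no filter, DESeq2 1.42.0, limma-trend on log2 of the deposited TPM values with pseudocounts of 1 and 0.1, a replicate block, only the libraries compared, groups from the genotype field, each library left out in turn, an estimated correlation for the lists, and, chosen after seeing the data, a fit without the library labelled 3D dSRF 1 and genes with a symbol outside the MHC region. Other splits of the libraries were counted, all 10 for comparisons of 2 groups and 40 of 200 for interactions. Figures and text were made with Python 3.11.15.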

Results

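Total RNA libraries were sequenced from MDA-MB-231, a human breast cancer line with mesenchymal features, in 4 engineered lines. One was a control line. The others overexpressed wild-type MRTF-A (WT) or 1 of 2 mutants that the titles call dSAP and dSRF, abbreviations that the labels do not spell out. MRTF-A, encoded by MRTFA, is an actin-regulated coactivator of the transcription factor SRF. All lines, control included, are labelled as treated with 1 ug/ml doxycycline for 72 h. Each line was grown in plates (2D) or on top of matrigel, a basement membrane gel (3D), with 3 libraries per line and culture, 24 in all. The labels do not say whether the replicates were separate cultures. 14986 genes had enough counts to be tested. The aim stated with the series is to see how MRTF-A overexpression changes the transcriptome. Values after a gene are log2 fold changes with the standard error of the fit (n = 3 per group), unless another unit is given. Counts of members of the gene lists are over all genes tested. Where no second count follows, the count adjusted over the list alone was the same.

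The induced gene was measured first, since the titles and the genotype field disagree for 16 of the 24 libraries. MRTFA (ENSG00000196588, chromosome 22, 40410281 to 40636702, GRCh38) stood at 37.5 ± 2.21 CPM (mean ± SD) in 2D control and at 29.2 ± 0.352 CPM in 3D control. In 2D it reached 4740 ± 195 CPM in WT, 9141 ± 442 in dSAP and 3237 ± 107 in dSRF. In 3D it reached 4516 ± 85.3 CPM in WT and 10504 ± 294 in dSAP. The 3D dSRF libraries were uneven: those labelled 2 and 3 held 4840.3 and 4857 CPM, the library labelled 3D dSRF 1 only 664. The highest library titled control held 39.1 CPM and the lowest other the 664 of that library, so the groups here follow the titles. The rises over control were 6.98 ± 0.51, 7.93 ± 0.53 and 6.43 ± 0.49 in 2D WT, dSAP and dSRF, and 7.27 ± 0.51, 8.49 ± 0.54 and 6.89 ± 0.51 in 3D. Between dSAP and WT the difference was 0.95 ± 0.39 (adjusted p = 0.124) in 2D and 1.22 ± 0.39 in 3D (adjusted p = 0.0489, a call lost under RLE size factors, on the TPM values, with replicate as a block or without any 1 of the 6 libraries compared). The library labelled 3D dSRF 1 widens the spread of MRTFA in the common fit, and without it these values were called in 2D (adjusted p = 2.49e-14) and 3D (adjusted p = 1.38e-16).

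**Figure D1:**
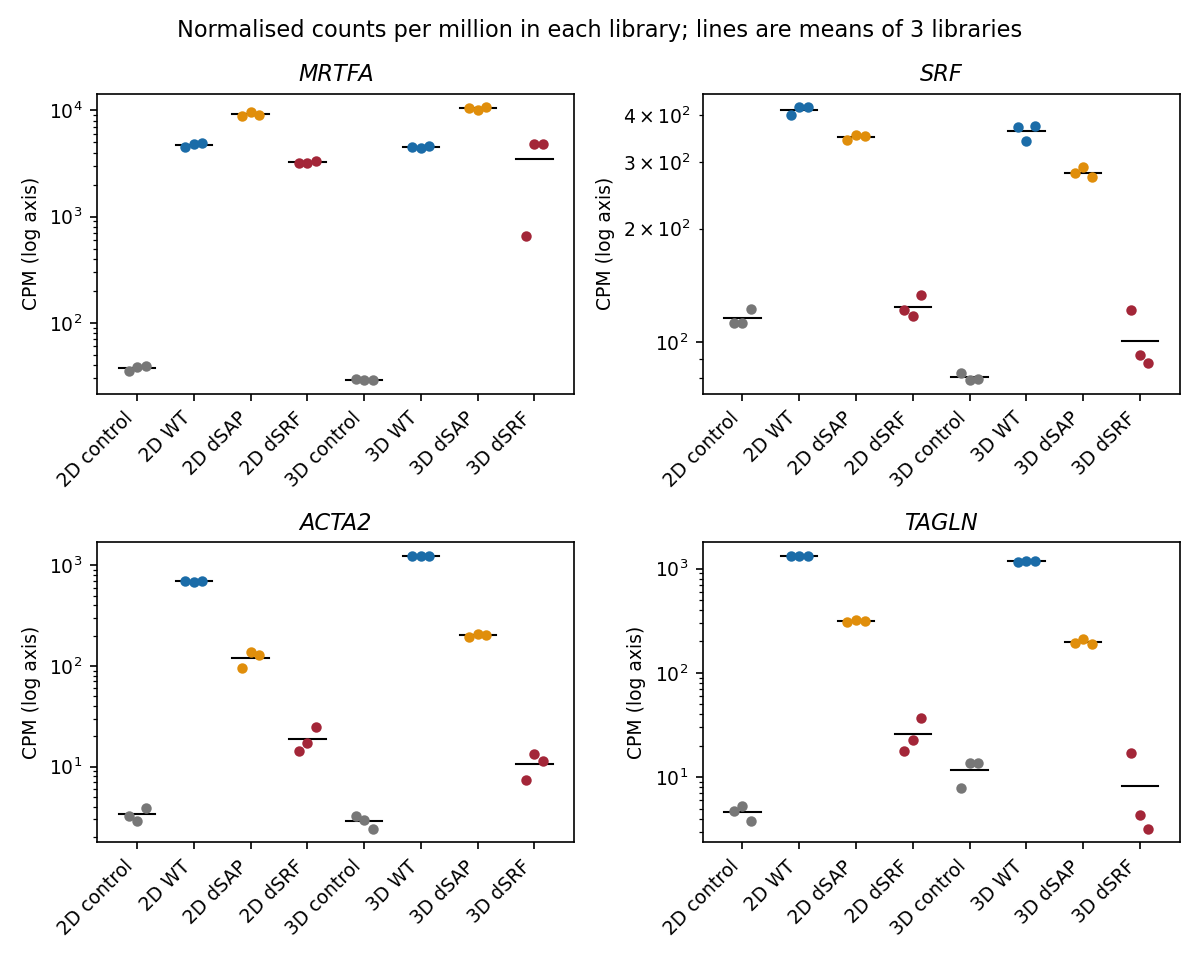
Normalised expression in CPM (log axis) of MRTFA, SRF, ACTA2 and TAGLN in each of the 24 libraries, by line and culture. Points are libraries and lines are means of 3. MRTFA was far above control in each overexpressing group and uneven in 3D dSRF, while ACTA2 and TAGLN were highest in WT, lower in dSAP and lowest of the overexpressing lines in dSRF.

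The main axis of variation set the dSRF line apart. The first principal component held 45% of the variance and separated dSRF from the other lines. On the second, with 17.5%, the 2D libraries of each line scored above its 3D libraries, and WT and dSAP above control of the same culture. The library labelled 3D dSRF 1 lay apart from its group: its log2 CPM correlated across genes with the mean of 2D dSRF at r = 0.971 and with the other 3D dSRF libraries at r = 0.952. Values without this library are given beside many of the 3D dSRF results. That alternative was chosen after seeing the data.

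**Figure D2:**
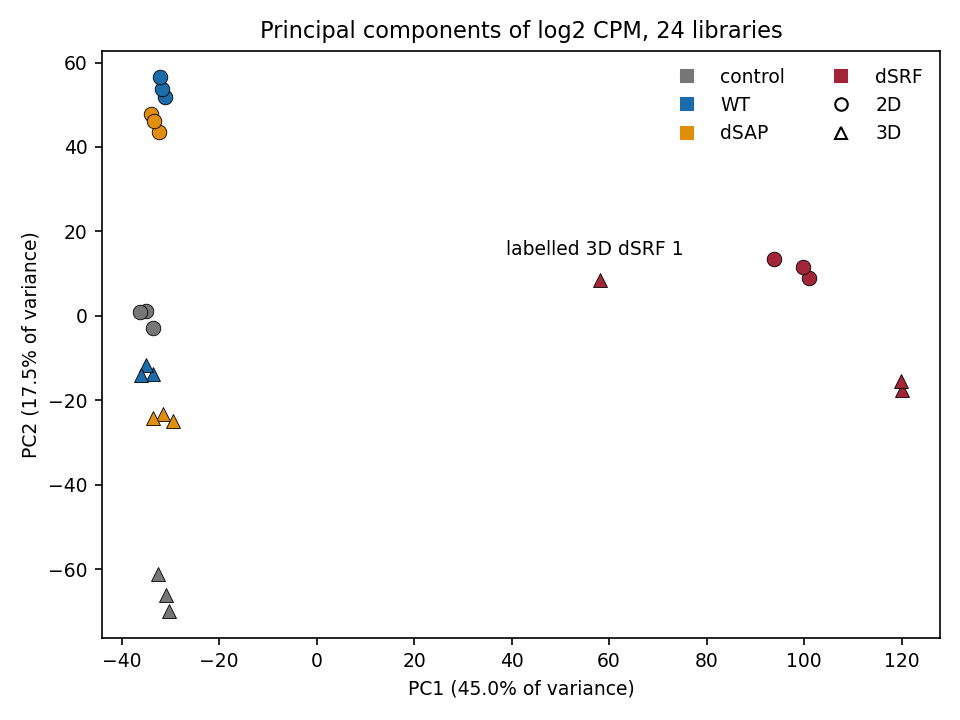
First and second principal components of log2 CPM over the 24 libraries, with lines as colours, 2D as circles and 3D as triangles. The dSRF libraries sit at PC1 scores of 58.1 to 120.0 and all others below 0. The library labelled 3D dSRF 1 is the lowest of the dSRF scores.

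In 2D, contractile and cytoskeletal genes that SRF is known to drive were higher in the WT line than in control. ACTG2, smooth muscle gamma actin, went from 0.0505 ± 0.0487 CPM (3 counts over the group) to 1092 ± 16.3. MYL7, a cardiac myosin light chain, rose at least 883-fold and KCNMB1, a potassium channel subunit of smooth muscle, at least 474-fold from 0 counts in control (lower bounds against a floor of 3 counts per group). TAGLN, an actin-binding protein of smooth muscle, rose by 8.16 ± 0.46 and ACTA2, smooth muscle alpha actin, by 7.68 ± 0.23. KRT17, a basal keratin, rose by 11.60 ± 0.43 and LMOD1, which nucleates smooth muscle actin filaments, by 9.65 ± 0.34. In total 5891 genes changed, 3012 higher and 2879 lower, 1215 of them by at least 2-fold. ACTC1, cardiac alpha actin, had 0.0557 ± 0.00789 CPM in control and 22.1 ± 2.02 in WT, and GARIN1B 0.0538 ± 0.0494 and 38.1 ± 2.03.

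Other fixed genes moved the same way in 2D WT: calponin CNN1 by 4.63, the myosin light chain MYL9 by 3.88, the focal adhesion gene VCL by 1.54, SRF itself by 1.84, the matrix glycoprotein TNC by 5.85, CCN1 by 1.21 and CCN2 by 2.90. MRTFB, the paralogue of MRTFA, fell (-0.55). The largest falls included ATOH8 (-5.30), a bHLH transcription factor, and ID1 (-4.01), an inhibitor of such factors that BMP signalling induces. NGFR, the low-affinity neurotrophin receptor (-3.85), SOST, which encodes the Wnt inhibitor sclerostin (-3.33), GGT5 (-3.66) and the interferon-inducible GTPase GBP4 (-3.35) fell as well. TMEM130 dropped to 0.0433 ± 0.0378 from 1.05 ± 0.236 CPM and NPY4R to 0.0637 ± 0.110 from 1.07 ± 0.174. RNF39, in the MHC region of chromosome 6, rose by 8.89 ± 1.53, but genes of that region are uncertain here because the reference can hold alternative copies of it. The calls of GBP4 and MRTFB were lost on log2(TPM + 1) (adjusted p = 0.0857 and 0.111).

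Among the lists, cytoskeletal MRTF/SRF targets led in 2D WT: 30 of 32 rose and 1 fell, median 1.82, adjusted p = 1.55e-26, and adjusted p = 0.0303 with an estimated correlation. CALD1, TPM4 and CSRP1 rose by 2.09, 1.74 and 2.39. Of the ATF4 and unfolded protein response genes 18 of 22 rose and 1 fell, 19 and 1 adjusted over the list alone, median 0.96, adjusted p = 1.70e-10 (adjusted p = 0.00411 with an estimated correlation), with the serine synthesis gene PSAT1 at 1.91, asparagine synthetase ASNS at 1.33 and CHAC1 at 2.20. Of the immediate early genes 9 of 16 rose and 0 fell, median 1.23, adjusted p = 1.55e-04 (adjusted p = 0.0719 with an estimated correlation; median 0.49 on log2(TPM + 1)), led by FOSB (3.19) and DUSP1 (1.98). Of the cholesterol synthesis genes 14 of 23 rose and 2 fell, 15 and 2 adjusted over the list alone, median 0.41, adjusted p = 1.27e-04 (adjusted p = 0.237 with an estimated correlation).

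Matrix and adhesion lists also went up in 2D WT. Of the ECM structural genes 15 of 31 rose and 5 fell, median 0.57, adjusted p = 0.00103 (adjusted p = 0.186 with an estimated correlation), with VCAN at 6.53 and fibronectin FN1 at 3.56. Of the integrins 6 of 15 rose and 3 fell, median 0.38, adjusted p = 0.0319 (adjusted p = 0.358 with an estimated correlation; median 0.15 on log2(TPM + 1)), with ITGB3 at 3.33 and ITGA5 at 3.25. Of the cell migration regulators 15 of 30 rose and 4 fell, 15 and 5 adjusted over the list alone, median 0.24, adjusted p = 0.00236 (adjusted p = 0.432 with an estimated correlation), MSN at 1.13 against S100A4 at -2.18. Of the epithelial markers 8 of 18 rose and 0 fell, median 0.39, adjusted p = 0.0312 (adjusted p = 0.591 with an estimated correlation), led by P-cadherin CDH3 (4.27). Proliferation genes went down: for mitosis genes 0 of 30 rose and 13 fell, median -0.40, adjusted p = 9.53e-04, and for DNA replication genes 0 of 28 rose and 13 fell, median -0.43, adjusted p = 0.00200, with CENPF at -0.48 and MCM2 at -0.66. Estimated correlations gave them adjusted p = 0.774 and 0.789. Beside them, ribosomal protein genes (0 of 31 rose and 13 fell, 0 and 14 adjusted over the list alone, median -0.24, adjusted p = 8.61e-04) and replication-dependent histone genes (0 of 17 rose and 11 fell, 0 and 13 adjusted over the list alone, median -0.92, adjusted p = 0.00238) went down. These lists had adjusted p = 0.743 and 0.740 with an estimated correlation. Histone messages mostly lack poly(A) tails, so their share can follow the library type. On the TPM values 1980 genes were called higher and 3252 lower, against 3012 and 2879 on the counts. The median of all genes was -0.090 on the TPM values and -0.024 on the counts.

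In 3D, wild-type MRTF-A also raised contractile genes, and 5244 genes changed (2698 higher, 2546 lower, 1154 by at least 2-fold). ACTG2 rose at least 24907-fold, MYL7 at least 689-fold and MGAM, maltase-glucoamylase, at least 421-fold from 0 counts in control. ACTA2 rose by 8.76 ± 0.24, TAGLN by 6.64 ± 0.42 and KRT17 by 9.67 ± 0.42. Low control levels precluded a fold for LMOD1 (0.0361 ± 0.0315 CPM in control, 61.4 ± 2.71 in WT), ACTC1 (0.0167 ± 0.0290 and 21.6 ± 0.928), GARIN1B (0.0167 ± 0.0290 and 15.2 ± 0.546) and the MHC-region gene RNF39 (0.0167 ± 0.0290 and 19.7 ± 1.55). CNN1 had 0.0334 ± 0.0579 and 0.329 ± 0.188 CPM. SRF rose by 2.17, MYL9 by 4.00, VCL by 2.18, CCN1 by 2.18, CCN2 by 3.62 and TNC by 4.21. The largest falls included the amino acid transporter SLC43A2 (-4.19; -8.89 without 3D WT 2), CFAP157 (-3.80), TMEM52B (-3.54), the potassium channel KCNN3 (-3.14), OLR1, a receptor for oxidised LDL (-2.99), and ZBTB7C (-2.97). KLRC2 and KLRC3, near-identical natural killer receptor genes whose reads are hard to part, stood at -3.26 and -3.12.

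The lists in 3D WT were led by cytoskeletal MRTF/SRF targets again (31 of 32 rose and 0 fell, median 2.17, adjusted p = 1.40e-34; adjusted p = 0.0108 with an estimated correlation). TGFB1I1 rose by 2.40. ECM structural genes (18 of 31 rose and 3 fell, 18 and 4 adjusted over the list alone, median 0.80, adjusted p = 1.88e-05; adjusted p = 0.0689 with an estimated correlation) included the basement membrane collagens COL4A1 (1.99) and COL4A2 (1.01). Integrins (7 of 15 rose and 3 fell, 8 and 3 adjusted over the list alone, median 0.32, adjusted p = 0.0197) included ITGA5 (3.63), epithelial markers (8 of 18 rose and 0 fell, median 0.52, adjusted p = 0.00296) CDH3 (5.25) and KRT7 (1.00). An estimated correlation gave adjusted p = 0.313 and 0.467. YAP/TEAD targets (10 of 22 rose and 1 fell, 10 and 2 adjusted over the list alone, median 0.48, adjusted p = 0.00918) and cell migration regulators (13 of 30 rose and 5 fell, median 0.19, adjusted p = 0.00760; median 0.055 on log2(TPM + 1)) rose on balance, CRIM1 by 1.02 and ARPC5 by 1.47. Estimated correlations gave them adjusted p = 0.736 and 0.489. Oxidative stress genes (2 of 17 rose and 9 fell, median -0.22, adjusted p = 0.0199) and ribosomal protein genes (0 of 31 rose and 24 fell, 0 and 26 adjusted over the list alone, median -0.36, adjusted p = 5.29e-07) went down, with the ferritin genes FTL at -1.22 and FTH1 at -1.22. In order, they had adjusted p = 0.445 and 0.572 with an estimated correlation. On the TPM values 1796 genes were called higher and 2545 lower.

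The effect of wild-type MRTF-A differed between cultures for 1376 genes (633 more positive in 3D, 743 more negative), 909 on the TPM values, and for 3636 without the library labelled 3D dSRF 1, which changes the estimate of spread. The stress response was part of it: ATF4 and unfolded protein response genes moved more negatively in 3D (1 of 22 higher and 16 lower, 1 and 17 adjusted over the list alone, median -0.83, adjusted p = 2.21e-19; adjusted p = 4.69e-04 with an estimated correlation), with the ER chaperone HSPA5 at -1.19 and DDIT3, a transcription factor of that response, at -2.21. Interferon response genes moved more positively (7 of 31 higher and 1 lower, 9 and 1 adjusted over the list alone, median 0.22, adjusted p = 0.00174; adjusted p = 0.0380 with an estimated correlation), led by IFIT2 (1.79) and IFIT3 (1.39). VCL rose further in 3D (0.64) and TNC rose less (-1.64). ACTA2 stood at 1.08, a call lost without any 1 of the 12 libraries compared (adjusted p = 0.0505 to 0.123).

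In 2D, contractile genes were higher in the dSAP line than in control as well. MYL7 rose at least 2262-fold, ALX1, a homeobox transcription factor, at least 143-fold and the hair keratin KRT34 at least 36.9-fold from 0 counts in control, and ACTG2 reached 549 ± 60.4 CPM. TAGLN rose by 6.09 ± 0.43, ACTA2 by 5.15 ± 0.22, KRT17 by 9.10 ± 0.47 and LMOD1 by 8.30 ± 0.35. GARIN1B reached 25.2 ± 1.25 CPM and ACTC1 16.1 ± 0.939. In total 4937 genes changed (2623 higher, 2314 lower, 874 by at least 2-fold). SRF rose by 1.60, CNN1 by 4.22, MYL9 by 3.98, VCL by 0.71, CCN1 by 0.80, CCN2 by 1.74 and TNC by 4.78. Falls included NGFR (-3.32), the epithelial sodium channel gene SCNN1A (-2.98), the neutrophil chemokine CXCL1 (-2.91) and GIMAP8 (-3.32; adjusted p = 0.216 on log2(TPM + 1)). TRIM26 and ATAT1 (at least 113-fold and at least 86.1-fold lower) lie in the uncertain MHC region. So does HLA-DRB1 (-3.44), whose dispersion was 0.776 of that of like genes.

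Of the cytoskeletal targets in 2D dSAP 27 of 32 rose and 0 fell, 29 and 2 adjusted over the list alone, median 1.43, adjusted p = 2.74e-25 (adjusted p = 0.0340 with an estimated correlation), with TGFB1I1 at 1.45. Of the ATF4 and unfolded protein response genes 14 of 22 rose and 1 fell, 15 and 1 adjusted over the list alone, median 0.46, adjusted p = 6.91e-06 (adjusted p = 0.0380 with an estimated correlation), with VLDLR at 1.06. Immediate early genes (5 of 16 rose and 0 fell, median 0.75, adjusted p = 0.00623; median 0.22 on log2(TPM + 1)) and cholesterol synthesis genes (13 of 23 rose and 2 fell, 14 and 2 adjusted over the list alone, median 0.27, adjusted p = 1.76e-04) rose on balance, FOSB by 3.24 and HMGCS1 by 0.58. These lists had adjusted p = 0.216 and 0.248 with an estimated correlation. Glycolysis genes (1 of 18 rose and 12 fell, median -0.39, adjusted p = 8.13e-05) and oxidative stress genes (1 of 17 rose and 8 fell, median -0.19, adjusted p = 0.0184) went down, with the glycolytic enzymes ENO1 at -0.65 and ALDOC at -1.48. In that order, adjusted p = 0.527 and 0.439 with an estimated correlation. Mitosis genes went down too (0 of 30 rose and 5 fell, 0 and 4 adjusted over the list alone, median -0.25, adjusted p = 0.00943; adjusted p = 0.817 with an estimated correlation). Beside them, ribosomal protein genes (0 of 31 rose and 25 fell, 0 and 28 adjusted over the list alone, median -0.34, adjusted p = 1.25e-08) and histone genes (0 of 17 rose and 7 fell, median -0.82, adjusted p = 0.00355) went down. In that order, adjusted p = 0.523 and 0.743 with an estimated correlation.

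In 3D the dSAP line changed 4435 genes (2475 higher, 1960 lower, 741 by at least 2-fold), or 6715 without the library labelled 3D dSRF 1. ACTG2 rose at least 12366-fold, MYL7 at least 2310-fold, MGAM at least 374-fold and ALX1 at least 123-fold from 0 counts in control. ACTA2 rose by 6.15 ± 0.22, TAGLN by 4.07 ± 0.38, MYL9 by 4.10, SRF by 1.80, TNC by 3.16, CCN1 by 1.79, CCN2 by 2.25 and VCL by 1.19. ACTC1, LMOD1 and GARIN1B reached 14.3 ± 2.51, 15.3 ± 3.42 and 6.25 ± 0.631 CPM. CNN1 (0.136 ± 0.0993 CPM) was not called (adjusted p = 0.287). KCNN3 fell (-3.59), as did the peptide transporter SLC15A1 (-2.81), SHISAL1 (-2.88; adjusted p = 0.0688 without 3D dSAP 1), OLR1 (-2.78), the granulocyte growth factor CSF3 (-2.40), ZBTB7C (-2.38), the readthrough locus KLRC4-KLRK1 (-2.73; adjusted p = 0.0573 on log2(TPM + 0.1)) and HLA-DRB1 (-2.42, MHC region).

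Cytoskeletal targets led the lists in 3D dSAP (29 of 32 rose and 0 fell, median 1.61, adjusted p = 2.42e-30; adjusted p = 0.0182 with an estimated correlation). PDLIM7 rose by 1.90. ECM structural genes rose on balance (15 of 31 rose and 4 fell, 16 and 4 adjusted over the list alone, median 0.35, adjusted p = 0.00892), with VCAN at 6.82, as did interferon response genes (15 of 31 rose and 3 fell, median 0.27, adjusted p = 0.0355), with RIGI at 2.37 and ISG15 at 1.13. An estimated correlation gave adjusted p = 0.313 and 0.174. The interferon call was lost without 3D control 3 (adjusted p = 0.0673). Hypoxia genes (1 of 25 rose and 11 fell, 1 and 14 adjusted over the list alone, median -0.35, adjusted p = 0.00109), glycolysis genes (0 of 18 rose and 11 fell, median -0.36, adjusted p = 3.01e-05), oxidative stress genes (2 of 17 rose and 8 fell, median -0.24, adjusted p = 0.00589) and NF-kB feedback genes (0 of 14 rose and 4 fell, median -0.18, adjusted p = 0.0173) went down, with VEGFA at -0.62, PKM at -0.49, FTH1 at -0.91 and NFKBIA at -0.61. Estimated correlations gave them adjusted p = 0.413, 0.498, 0.383 and 0.432. Shifts down were also called for mitosis (0 of 30 rose and 4 fell, 0 and 3 adjusted over the list alone, median -0.23, adjusted p = 0.0230), ribosomal protein genes (0 of 31 rose and 26 fell, 0 and 27 adjusted over the list alone, median -0.36, adjusted p = 5.58e-10) and histone genes (0 of 17 rose and 0 fell, median -0.54, adjusted p = 0.0258). An estimated correlation gave adjusted p = 0.825, 0.489 and 0.807. Fibroblast markers rose on balance (2 of 5 rose and 0 fell, median 1.13, adjusted p = 0.0373; adjusted p = 0.377 with an estimated correlation), COL3A1 by 4.17 and LUM by 1.49.

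Set directly against WT, dSAP had lower levels of several contractile genes in each culture. In 2D, ACTA2 stood at -2.53 ± 0.17, TAGLN at -2.07 ± 0.33, KCNMB1 at -3.93 ± 0.31 and IRAG1, a regulator of smooth muscle calcium release, at -3.88 ± 0.46. In 3D, ACTA2 stood at -2.61 ± 0.17, TAGLN at -2.57 ± 0.34, KCNMB1 at -5.89 ± 0.40, IRAG1 at -4.42 ± 0.40 and KRT17 at -3.22 ± 0.23. MYL9 did not follow, at 0.10 ± 0.23 (adjusted p = 0.847) in 2D and 0.10 ± 0.23 (adjusted p = 0.848) in 3D, CNN1 did not pass the test (adjusted p = 0.592 and 0.375). MYL7 was higher in dSAP (1.37 and 1.75). The MYL7 calls were lost with DESeq2 (adjusted p = 0.434 in 2D and 0.306 in 3D) and on log2(TPM + 0.1) (0.353 and 0.253). In 2D the call was also lost on log2(TPM + 1) (0.0555), with replicate as a block (0.0570) and without any 1 of the libraries compared but 2D dSAP 1 (0.0525 to 0.0729). Higher in dSAP were ALX1 (at least 122-fold in 2D; 6.85 ± 0.80 against 0.0158 ± 0.0274 CPM in 3D), GRAMD1B (3.57 and 3.97), SYTL5 (2.73 and 2.89) and VAV1, a guanine nucleotide exchange factor best known from blood cells (2.34 and 4.76). The collagenase MMP8 was higher in 2D (2.45), and PSG3, of a family of near-identical pregnancy glycoprotein genes, in 3D (3.14). TRIM26, ATAT1 and RNF39 of the MHC region were also among the largest differences: at least 164-fold and at least 37.3-fold lower in 2D, and -3.11 in 3D. The ATAT1 call was lost without 2D WT 2 or any 2D dSAP library (adjusted p = 0.0712 to 0.0916), with replicate as a block (0.0594) or on log2(TPM + 1) (0.107). That of RNF39 was lost without any 1 of the 6 libraries (adjusted p = 0.0871 to 0.145), with DESeq2 (0.486) or on log2(TPM + 0.1) (0.137). That of GRAMD1B in 2D was lost without 2D WT 1 or 2D WT 2 (adjusted p = 0.0523 and 0.0576). GRAMD1B was also lost on log2(TPM + 1), with adjusted p = 0.0550 in 2D and 0.0634 in 3D. Counts were 1919 genes in 2D (763 higher in dSAP, 1156 lower) and 1810 in 3D (817 and 993), and 1171 and 1186 without 2D dSAP 1 and 3D dSAP 1.

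Several lists were also lower in 2D dSAP than in WT. These were cytoskeletal targets (0 of 32 higher and 18 lower, 1 and 23 adjusted over the list alone, median -0.45, adjusted p = 1.21e-14), ECM structural genes (0 of 31 higher and 16 lower, 1 and 16 adjusted over the list alone, median -0.31, adjusted p = 9.43e-05; COL5A1 -0.61) and integrins (0 of 15 higher and 6 lower, 1 and 6 adjusted over the list alone, median -0.40, adjusted p = 1.03e-04; ITGA5 -1.21). Estimated correlations gave them adjusted p = 0.107, 0.0972 and 0.0644. ATF4 and unfolded protein response genes were lower too (1 of 22 higher and 13 lower, 1 and 18 adjusted over the list alone, median -0.37, adjusted p = 4.92e-11; adjusted p = 0.00386 with an estimated correlation), with HSP90B1 at -0.63. Lower as well were glycolysis (0 of 18 higher and 9 lower, 0 and 11 adjusted over the list alone, median -0.27, adjusted p = 1.38e-07; GAPDH -0.51) and immediate early genes (0 of 16 higher and 5 lower, median -0.36, adjusted p = 0.00346, -0.051 on log2(TPM + 1); ATF3 -0.73), and cytokines and chemokines (1 of 19 higher and 4 lower, median -0.60, adjusted p = 0.00412; LIF -0.65). In order, they had adjusted p = 0.395, 0.196 and 0.479 with an estimated correlation. The list of MRTFA, SRF and their relatives (3 of 6 higher and 0 lower, 5 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.0157; adjusted p = 0.215 with an estimated correlation) was higher, with MRTFB at 0.34 (adjusted p = 0.50 on the TPM values).

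In 3D, cytoskeletal targets (0 of 32 higher and 20 lower, 0 and 22 adjusted over the list alone, median -0.56, adjusted p = 1.10e-22; adjusted p = 0.0380 with an estimated correlation) and ECM structural genes (2 of 31 higher and 13 lower, 2 and 16 adjusted over the list alone, median -0.39, adjusted p = 3.48e-06; adjusted p = 0.0473 with an estimated correlation) were lower in dSAP than in WT, with CALD1 at -0.90 and COL8A1 at -0.75. Integrins (0 of 15 higher and 6 lower, median -0.37, adjusted p = 6.98e-05; ITGA1 -1.47), YAP/TEAD targets (0 of 22 higher and 3 lower, median -0.20, adjusted p = 0.00400; CCN2 -1.37, lost without any 3D dSAP library with adjusted p = 0.0558 to 0.0673) and hypoxia genes (0 of 25 higher and 6 lower, 0 and 7 adjusted over the list alone, median -0.18, adjusted p = 4.00e-04) were lower. In order, they had adjusted p = 0.0577, 0.687 and 0.385 with an estimated correlation. Beside them, histone genes (0 of 17 higher and 0 lower, median -0.44, adjusted p = 0.0386; adjusted p = 0.815 with an estimated correlation) lost the call without 3D WT 1, 3D WT 2 or 3D dSAP 2 (adjusted p = 0.0653, 0.0877 and 0.0870) and under RLE size factors (adjusted p = 0.0565). Without the library labelled 3D dSRF 1 in the fit the counts of called genes were 4220 in 2D and 4149 in 3D. On the TPM values the balance turned to higher in dSAP: 1404 higher and 455 lower in 2D, 1125 and 505 in 3D.

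The effect of dSAP differed between cultures for 350 genes (170 more positive in 3D, 180 more negative), 1738 without the library labelled 3D dSRF 1, 200 on the TPM values, and 206, 225 or 217 without 2D dSAP 3, 3D dSAP 2 or 3D dSAP 3. ATF4 and unfolded protein response genes moved more negatively in 3D (0 of 22 higher and 10 lower, 0 and 14 adjusted over the list alone, median -0.40, adjusted p = 6.23e-16; adjusted p = 8.21e-04 with an estimated correlation), HERPUD1 at -0.76, and interferon response genes more positively (6 of 31 higher and 0 lower, 9 and 0 adjusted over the list alone, median 0.24, adjusted p = 1.38e-07; adjusted p = 0.00105 with an estimated correlation), OASL at 1.42. FOSB, an AP-1 subunit, showed the most negative difference (-3.24), and SERPINE2, a protease inhibitor, stood at -1.69. The calls of HERPUD1 and SERPINE2 were lost on log2(TPM + 1) (adjusted p = 0.0889 and 0.102) and that of OASL on log2(TPM + 0.1) (adjusted p = 0.0534).

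The dSRF line differed from control in more genes than either other line. In 2D, 9885 genes changed (5165 higher, 4720 lower, 3389 by at least 2-fold). IGFL1 rose at least 15717-fold, the cytochrome P450 gene CYP4B1 at least 2452-fold, the calcium-binding protein gene NECAB1 at least 858-fold and KLHDC7A at least 734-fold from 0 counts in control. LCE3D (at least 664-fold) and CRCT1 (at least 474-fold), from the epidermal differentiation cluster, the phosphate transporter SLC34A2 (at least 423-fold) and the metallothionein MT1B (at least 322-fold) also rose from 0. LCE3D and MT1B belong to families of near-identical genes. ACTA2 rose by 2.48 ± 0.22, TAGLN by 2.50 ± 0.42 and TNC by 1.15 ± 0.24. SRF (0.10 ± 0.083, adjusted p = 0.284), CNN1 (0.39 ± 0.58, adjusted p = 0.579), MYL9 (0.067 ± 0.23, adjusted p = 0.820), VCL (-0.026 ± 0.043, adjusted p = 0.623), CCN1 (0.40 ± 0.22, adjusted p = 0.116) and CCN2 (0.26 ± 0.36, adjusted p = 0.547) did not pass the test, and MRTFB (-0.82) fell. Among the largest falls were CA9, a carbonic anhydrase induced by hypoxia (-4.99), the glycolytic enzyme ALDOC (-4.62), C1QL1 (-4.96), PPFIA4 (-4.50) and LGALS12 (-4.28). C4B and BAG6 (at least 151-fold and at least 38.4-fold lower) and PRRC2A (-4.20) lie in the MHC region and are uncertain. The BAG6 call was lost without any 1 of the 6 libraries (adjusted p = 0.0530 to 0.0979) or with DESeq2 (0.0707). That of PRRC2A was lost without 2D dSRF 2 or 2D dSRF 3 (adjusted p = 0.0547 and 0.0630; -9.34 without 2D dSRF 1). SRF and CCN1 were called on the TPM values (adjusted p = 0.0150 and 0.0366), and CCN1 and CCN2 at the same values without the library labelled 3D dSRF 1, which widens their spread in the common fit (adjusted p = 4.59e-08 and 6.49e-04).

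Proliferation genes were down as a block in 2D dSRF. For mitosis genes 0 of 30 rose and 30 fell, median -1.55, adjusted p = 6.84e-10, CCNB1 at -1.01, and for DNA replication genes 1 of 28 rose and 24 fell, 1 and 26 adjusted over the list alone, median -0.76, adjusted p = 4.46e-04, PCNA at -0.87. These lists had adjusted p = 0.532 and 0.752 with an estimated correlation. Hypoxia genes (3 of 25 rose and 20 fell, median -1.26, adjusted p = 2.75e-05; DDIT4 -3.31) and glycolysis genes (0 of 18 rose and 16 fell, median -1.07, adjusted p = 7.43e-08; LDHA -1.81) also went down. These lists had adjusted p = 0.298 and 0.386 with an estimated correlation. Epithelial markers went up (11 of 18 rose and 2 fell, 12 and 2 adjusted over the list alone, median 1.29, adjusted p = 0.0178), with the simple-epithelium keratins KRT8 at 3.30 and KRT18 at 3.21, as did p53 targets (12 of 17 rose and 4 fell, median 0.73, adjusted p = 0.0234), with the death receptor FAS at 4.49 and BTG2 at 3.04. In order, they had adjusted p = 0.542 and 0.394 with an estimated correlation. ATF4 and unfolded protein response genes (15 of 22 rose and 4 fell, median 0.52, adjusted p = 0.00389; PSAT1 3.03) and immediate early genes (11 of 16 rose and 2 fell, 11 and 3 adjusted over the list alone, median 0.82, adjusted p = 0.0414; FOSB 4.10) went up, the latter not without 2D dSRF 3 (adjusted p = 0.0505) or the library labelled 3D dSRF 1 (0.0821). In that order, adjusted p = 0.199 and 0.386 with an estimated correlation. Beside these, ribosomal protein genes (0 of 31 rose and 29 fell, 0 and 31 adjusted over the list alone, median -0.46, adjusted p = 3.58e-06) and histone genes (0 of 17 rose and 17 fell, median -2.10, adjusted p = 3.68e-05) went down. In that order, adjusted p = 0.613 and 0.613 with an estimated correlation. Cytoskeletal targets were not called as a list (10 of 32 rose and 9 fell, median 0.020, adjusted p = 0.948).

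In 3D dSRF 9948 genes changed (5261 higher, 4687 lower, 3635 by at least 2-fold), and 11098 without the library labelled 3D dSRF 1, 9436 of them called in both fits. IGFL1 rose at least 9422-fold, CYP4B1 at least 964-fold, CRCT1 at least 911-fold, LCE3D at least 780.4-fold, the kinase gene MAPK4 at least 285-fold and MT1B at least 182-fold from 0 counts in control. These bounds include the library labelled 3D dSRF 1, where CRCT1, LCE3D and MAPK4 held 10.9, 2.88 and 1.59 CPM, against 79.0, 65.0 and 24.7 in 3D dSRF 2. KRT16, a keratin of stressed epidermis, went from 0.0388 ± 0.0336 to 336 ± 263 CPM and KLHDC7A from 0.0195 ± 0.0338 to 47.2 ± 38.2. CA9 (-6.87), C1QL1 (-4.97) and KLRC3 (-5.24) fell, to 5, 5 and 4 counts over the group. CA12 fell too (-4.69; -5.52 without that library), as did the oxygen-sensing hydroxylase EGLN3 (-4.62; -4.84), PPFIA4 (-4.99; -4.73) and RTN4RL2 (-4.73; -5.05). CCN1 rose by 3.58 (2.99 without it), CCN2 by 2.50 (1.34), ACTA2 by 1.90 (2.11), VCL by 0.68 (0.72) and SRF by 0.32 (0.16). TNC (-2.07; -2.48), MYL9 (-0.74; -1.29, not called without 3D dSRF 2 or 3D dSRF 3 with adjusted p = 0.0658 and 0.0676) and MRTFB (-1.2; -1.23) fell, and TAGLN stood at -0.47 ± 0.40 (adjusted p = 0.316), becoming a called fall without it (-1.65).

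Mitosis genes (0 of 30 rose and 30 fell, median -2.22, adjusted p = 9.80e-13; NUSAP1 -2.24) and DNA replication genes (0 of 28 rose and 28 fell, median -1.61, adjusted p = 2.13e-10; MCM4 -1.51) went down in 3D dSRF, and epithelial markers up (14 of 18 rose and 0 fell, median 2.65, adjusted p = 6.63e-06; KRT18 4.52, DSP 2.75). Their adjusted p with an estimated correlation was 0.484, 0.503 and 0.248, and without the library labelled 3D dSRF 1 7.16e-18, 3.40e-15 and 2.38e-07. Hypoxia (3 of 25 rose and 18 fell, 3 and 19 adjusted over the list alone, median -0.77, adjusted p = 3.62e-04), glycolysis (0 of 18 rose and 17 fell, median -0.60, adjusted p = 3.58e-06; LDHA -1.64) and oxidative stress genes (3 of 17 rose and 10 fell, median -0.62, adjusted p = 0.0259) went down, with adjusted p = 0.383, 0.458 and 0.465 with an estimated correlation and 0.00199, 1.63e-06 and 0.0172 without that library. Up went cholesterol synthesis (15 of 23 rose and 3 fell, median 0.48, adjusted p = 0.010), ATF4 and unfolded protein response (15 of 22 rose and 3 fell, median 0.61, adjusted p = 0.00412; CHAC1 4.26) and immediate early genes (11 of 16 rose and 1 fell, median 0.72, adjusted p = 0.0276; DUSP1 4.36), with adjusted p = 0.445, 0.201 and 0.358 with an estimated correlation and 0.00498, 0.00846 and 0.0666 without that library, where the last call is lost. Ribosomal protein genes (0 of 31 rose and 31 fell, median -0.47, adjusted p = 6.91e-06) and histone genes (0 of 17 rose and 17 fell, median -2.27, adjusted p = 4.42e-06; medians -1.24, -3.60 and -3.52 by library, -3.53 without that one) went down beside them (adjusted p = 0.618 and 0.560 with an estimated correlation). Without that library p53 targets became a call (adjusted p = 0.0498), from adjusted p = 0.0803 with it.

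**Figure D3:**
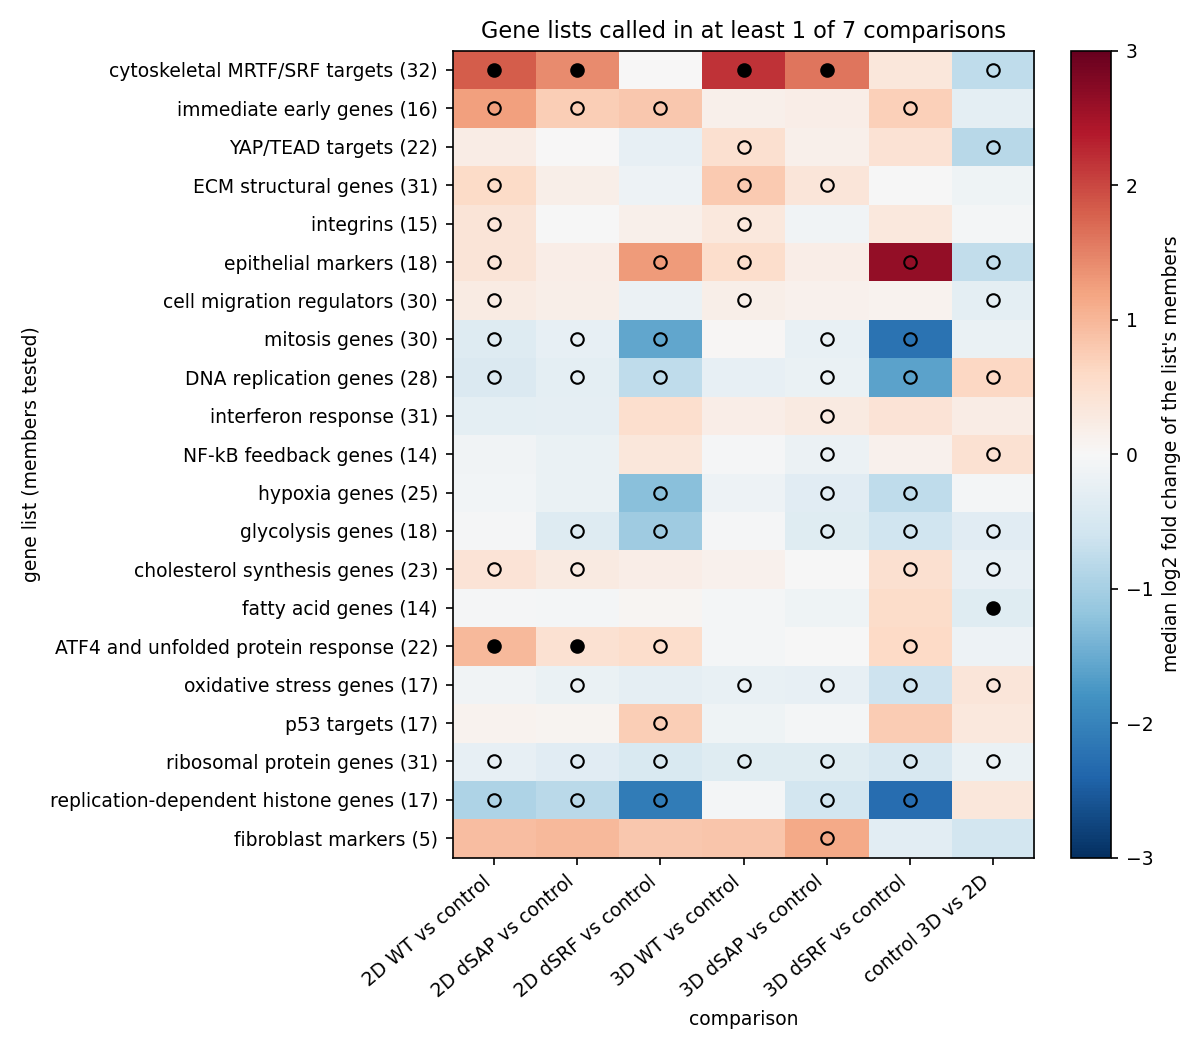
Median log2 fold change (colour) of each gene list called in at least 1 of 7 comparisons, with the number of members tested. Circles mark lists called with the preset correlation and filled circles those that also pass with an estimated one. Cytoskeletal MRTF/SRF targets rose in WT and dSAP (medians 1.43 to 2.17), and mitosis genes fell most in dSRF (-1.55 in 2D, -2.22 in 3D).

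Against WT, the dSRF line held low levels of contractile genes. In 2D, KCNMB1 stood at -7.62 ± 0.43, TAGLN at -5.66 ± 0.40 and ACTA2 at -5.20 ± 0.19, MYL9 at -3.81, CNN1 at -4.25 and SRF at -1.73. In 3D, LMOD1 stood at -8.82 ± 0.34 (-8.58 without the library labelled 3D dSRF 1), ACTG2 at -8.49 ± 0.62 (-11.11), KCNMB1 at -7.37 ± 0.46 (its 4 counts in 3D dSRF all came from that library) and ACTA2 at -6.86 ± 0.21 (-6.65). TRAC and GIPC3 were at least 44.3-fold and at least 40.2-fold lower in 3D. Among the genes highest over WT were IGFL1 (at least 13451-fold in 2D; 537 ± 245 against 0.0314 ± 0.0272 CPM in 3D), CYP4B1 (at least 2098-fold and at least 1064-fold), KLHDC7A (at least 628-fold and at least 890.3-fold) and LCE3D (at least 568-fold and at least 861-fold), with CRCT1 in 2D (at least 406-fold) and NECAB1 in 3D (at least 1000.3-fold). The 3D bounds include that library, where KLHDC7A and LCE3D held 3.18 and 2.88 CPM against 69.6 and 65.0 in 3D dSRF 2. Counts were 9594 in 2D (5039 higher in dSRF, 4555 lower) and 9869 in 3D (5129 and 4740; 11107 without that library).

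Of the cytoskeletal targets, 0 of 32 were higher and 32 lower in 2D dSRF than WT, median -1.92, adjusted p = 1.11e-17, and 1 of 32 were higher and 31 lower in 3D, median -1.89, adjusted p = 4.72e-14 (adjusted p = 0.0710 and 0.115 with an estimated correlation). ECM structural genes (6 of 31 higher and 19 lower, 7 and 19 adjusted over the list alone, median -1.02, adjusted p = 2.95e-04 in 2D; 5 of 31 higher and 18 lower, 6 and 18 adjusted over the list alone, median -0.80, adjusted p = 9.01e-04 in 3D) and mesenchymal markers (1 of 11 higher and 9 lower, median -1.50, adjusted p = 0.0183; 1 of 11 higher and 8 lower, median -0.97, adjusted p = 0.0312, and -1.64 without the library labelled 3D dSRF 1) were lower, FN1 by -1.96 and -2.14, while S100A4 was higher (3.37 and 2.00). These lists had adjusted p = 0.124, 0.180, 0.313 and 0.361 with an estimated correlation. Mitosis (median -1.09, adjusted p = 5.55e-07 in 2D; median -2.12, adjusted p = 7.47e-13 in 3D), hypoxia (median -1.24, adjusted p = 2.63e-06; median -0.50, adjusted p = 0.00166; medians -0.48 and -0.46 on log2(TPM + 1)), glycolysis (median -0.93, adjusted p = 3.83e-08; median -0.70, adjusted p = 1.41e-05) and histone genes (median -1.2, adjusted p = 0.0102; median -2.19, adjusted p = 9.82e-06, and -3.57 without that library) were lower in dSRF and p53 targets higher (median 0.58, adjusted p = 0.0155; median 0.85, adjusted p = 0.00975). An estimated correlation gave adjusted p = 0.618, 0.480, 0.205, 0.432, 0.386, 0.489, 0.779, 0.579, 0.377 and 0.356. Mitochondrial genome genes, a sign of RNA quality, were lower in 3D dSRF than WT (0 of 13 higher and 12 lower, median -0.89, adjusted p = 0.0206; adjusted p = 0.763 with an estimated correlation), a call that ended without the library labelled 3D dSRF 1 (adjusted p = 0.154). On the TPM values the 2D split was 6026 higher and 2996 lower, and the median of all genes moved by 0.18 in 2D and 0.10 in 3D.

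The mutants also differed from each other in contractile genes. In 2D, MYL7 (4.11 ± 0.42) and ACTG2 (4.08 ± 0.49) were higher in dSAP, as was the mast cell protease CPA3 (1.36 ± 0.148 against 0.0517 ± 0.0896 CPM). In 3D, MYL7 (7.48 ± 0.55; its 45 counts in dSRF all came from the library labelled 3D dSRF 1), ACTG2 (7.48 ± 0.60; 10.10 without that library) and LMOD1 (6.81 ± 0.37; 6.57) were higher in dSAP, and ALX1 (at least 142-fold) and the protease inhibitor SERPINB2 (at least 32.8-fold) were at 0 counts in dSRF. Lower in dSAP were IGFL1 (at least 14757-fold in 2D, at least 10103-fold in 3D), CRCT1 (at least 446-fold, at least 977-fold) and KLHDC7A (at least 689-fold, at least 865-fold), with CYP4B1 in 2D (at least 2302-fold) and NECAB1 in 3D (0.0163 ± 0.0282 against 52.5 ± 35.3 CPM). These 3D bounds include that library too, with 10.9 and 3.18 CPM of CRCT1 and KLHDC7A. Counts were 9739 in 2D (4700 higher in dSAP, 5039 lower) and 9699 in 3D (4771 and 4928; 10969 without that library).

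Higher in dSAP than dSRF in each culture were cytoskeletal targets (median 1.57, adjusted p = 1.83e-13 in 2D; median 1.40, adjusted p = 7.17e-08 in 3D), ECM structural (median 0.60, adjusted p = 0.00399; median 0.34, adjusted p = 0.0185), mitosis (median 1.22, adjusted p = 4.80e-08; median 1.88, adjusted p = 1.37e-11), DNA replication (median 0.51, adjusted p = 0.0264; median 1.44, adjusted p = 4.00e-09), hypoxia (median 1.03, adjusted p = 6.06e-04; median 0.44, adjusted p = 0.0271), glycolysis (median 0.73, adjusted p = 2.75e-05; median 0.44, adjusted p = 0.00278) and histone genes (median 1.36, adjusted p = 0.00354; median 1.75, adjusted p = 6.99e-05, and 3.06 without the library labelled 3D dSRF 1). Their adjusted p with an estimated correlation ran from 0.124 to 0.824. Lower were epithelial markers (median -1.14, adjusted p = 0.0447; median -1.93, adjusted p = 1.45e-05) and p53 targets (median -0.77, adjusted p = 0.00702; median -0.75, adjusted p = 0.010). Estimated correlations gave them adjusted p = 0.618, 0.289, 0.322 and 0.356. In 3D, mitochondrial genome genes were higher (median 0.88, adjusted p = 0.0202; adjusted p = 0.763 with an estimated correlation). Leaving out 1 library ended several of these calls. In 2D these were epithelial markers (without 2D dSAP 1 or 2D dSRF 1; adjusted p = 0.0564 and 0.0559) and DNA replication (without 2D dSAP 1; adjusted p = 0.0675). In 3D, without the library labelled 3D dSRF 1, they were ECM structural, hypoxia and mitochondrial genome genes (adjusted p = 0.105, 0.0958 and 0.157).

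The dSRF effect differed between cultures for 4379 genes (2197 more positive in 3D, 2182 more negative) and for 6680 without the library labelled 3D dSRF 1, 4161 of them called in both fits. With only the libraries compared 2642 were called, and on the TPM values 1354 were more positive and 1984 more negative. A fall in 3D control alone makes this difference positive, and a rise negative. Of genes that fell in control, SOST stood at 5.23 (5.58 without that library), DMBT1 at 6.03 (6.37) and KISS1 at 4.90 (2.58). The chemokine CXCL10, which rose in control, stood at -5.11 (-5.61). YAP/TEAD targets (13 of 22 higher and 0 lower, 14 and 0 adjusted over the list alone, median 0.69, adjusted p = 4.65e-06; CCN1 3.18) and epithelial markers (12 of 18 higher and 1 lower, 14 and 1 adjusted over the list alone, median 0.96, adjusted p = 5.98e-05) moved more positively. In order, they had adjusted p = 0.495 and 0.334 with an estimated correlation. DNA replication (0 of 28 higher and 17 lower, 0 and 24 adjusted over the list alone, median -0.93, adjusted p = 3.33e-09) and NF-kB feedback genes (0 of 14 higher and 8 lower, 0 and 9 adjusted over the list alone, median -0.55, adjusted p = 2.28e-04) moved more negatively. In that order, adjusted p = 0.532 and 0.199 with an estimated correlation. Without that library the 4 lists had adjusted p = 6.86e-05, 8.29e-10, 1.97e-22 and 8.64e-07 and medians 0.32, 1.13, -1.45 and -0.54.

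Culture itself changed 7097 genes in the control line (3446 higher in 3D, 3651 lower, 1395 by at least 2-fold). NPPB, KISS1, SOST and DMBT1 were among the largest falls: NPPB, which encodes a natriuretic peptide, went from 8.64 ± 0.367 to 0.0390 ± 0.0675 CPM, and DMBT1, KISS1 and SOST stood at -5.66 ± 0.34, -5.63 ± 0.84 and -5.34 ± 0.62. CLIC5 fell (-4.66), and the cytokine receptor subunit CSF2RB went from 2.00 ± 0.458 to 0.0502 ± 0.0869 CPM. PSG6 (1.64 ± 0.699 to 0.0581 ± 0.0580 CPM), the defensin DEFB103B (1.61 ± 0.403 to 0.0388 ± 0.0336) and the rising gonadotropin gene CGB8 (0.0324 ± 0.0561 to 5.73 ± 1.42) have near-identical copies and are uncertain. From 0 counts in 2D, CELF6, a splicing regulator, rose at least 45.2-fold and SHISAL1 at least 19.1-fold. PLEKHG4B (5.18), N4BP3 (4.71), HHIPL2 (4.07), IGFN1 (3.83) and CXCL10 (3.82) rose. MRTFA stood at -0.36 ± 0.42 (adjusted p = 0.514), called without the library labelled 3D dSRF 1 (adjusted p = 4.24e-06), SRF fell (-0.52), as did VCL (-0.79), CCN1 (-3.39) and CCN2 (-2.82).

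In 3D the control line lowered cytoskeletal targets (3 of 32 rose and 23 fell, 3 and 24 adjusted over the list alone, median -0.76, adjusted p = 7.17e-08; ACTN1 -0.87), YAP/TEAD targets (0 of 22 rose and 17 fell, 0 and 18 adjusted over the list alone, median -0.84, adjusted p = 4.50e-07; ANKRD1 -3.90), epithelial markers (1 of 18 rose and 15 fell, median -0.73, adjusted p = 2.56e-04; KRT7 -1.90) and cell migration regulators (5 of 30 rose and 17 fell, median -0.30, adjusted p = 0.00434; RHOA -0.41). These lists had adjusted p = 0.313, 0.450, 0.383 and 0.465 with an estimated correlation. Lipid genes fell too: fatty acid genes (0 of 14 rose and 10 fell, median -0.35, adjusted p = 2.56e-04; adjusted p = 0.0380 with an estimated correlation), with the desaturase SCD at -1.98 and fatty acid synthase FASN at -1.45, and cholesterol synthesis genes (2 of 23 rose and 12 fell, median -0.24, adjusted p = 0.00183; adjusted p = 0.370 with an estimated correlation). DNA replication (21 of 28 rose and 0 fell, 22 and 0 adjusted over the list alone, median 0.61, adjusted p = 5.33e-06; CCNE1 1.33), NF-kB feedback (9 of 14 rose and 0 fell, 10 and 0 adjusted over the list alone, median 0.45, adjusted p = 2.95e-04; TRAF1 1.46) and oxidative stress genes (8 of 17 rose and 2 fell, 9 and 2 adjusted over the list alone, median 0.36, adjusted p = 0.00232; NQO1 1.44) rose. In that order, adjusted p = 0.643, 0.205 and 0.332 with an estimated correlation. Glycolysis (2 of 18 rose and 12 fell, median -0.35, adjusted p = 0.00918; SLC16A3 -0.72) and ribosomal protein genes (0 of 31 rose and 13 fell, 0 and 12 adjusted over the list alone, median -0.19, adjusted p = 0.00895) went down. An estimated correlation gave adjusted p = 0.705 and 0.807. On the TPM values 3735 genes were called higher and 2273 lower, against 3446 and 3651 on the counts.

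**Figure D4:**
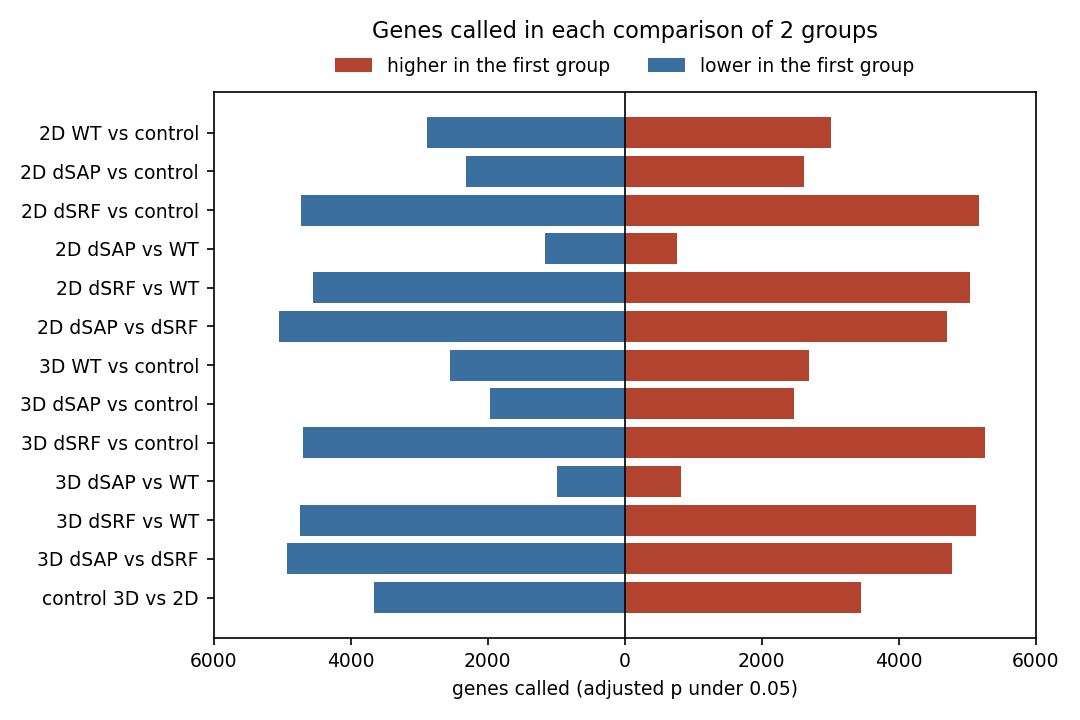
Number of genes called higher (right) and lower (left) in the first group of each comparison of 2 groups, at an adjusted p under 0.05 over 14986 genes. The comparisons with dSRF hold 9594 to 9948 called genes, dSAP against WT 1810 and 1919.

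The calls of the lines overlapped. In 2D, 2053 of the 3012 genes higher in WT were also higher in dSAP and 1673 in dSRF. Of the 2879 lower, 1703 were lower in dSAP and 1596 in dSRF. Independent lists of these sizes would share 527, 1038, 445 and 907 in that order. Genes called in opposite directions were 20 and 9 between WT and dSAP, and 592 and 534 between WT and dSRF. In 3D, 1826 of the 2698 genes higher in WT were higher in dSAP and 1550 in dSRF, and 1460 and 1358 of the 2546 lower (446, 947, 333 and 796 for independent lists). Between dSAP and dSRF 1436 higher and 1312 lower genes were shared in 2D and 1466 and 1140 in 3D, against 904, 729, 869 and 613. In 5 simulations of unchanged groups against the same controls the overlap was 0. With 3 control libraries per culture, what the shared controls add to these overlaps is not separated here. Of the 3012 genes higher in 2D WT, 860 were lower in dSAP than in WT and 29 higher, and in 3D 776 and 66 of 2698. Choosing genes by their WT value favours lower values in the mutant.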

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

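The tests of the library labelled 3D dSRF 1, of the construct level and of the 9p21 genes were chosen only after the result was seen, as was the fit without that library. The results listed here passed a test of the difference between cultures itself, the edgeR interaction of construct and culture. Positive values mean a larger, or less negative, change from control in 3D than in 2D. A shift of control between the cultures can make such a difference alone. Values of genes with 3 counts or fewer in a group (TRAC, FLT1, CST2, ATAT1, NPPB, DEFB103B, CELF6, CDH16, PAPPA2 and IL36G) depend on the prior count of the fit.

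The WT effect differed between cultures for 1376 genes. It was more positive in 3D for TRAC by 4.68, FLT1 by 4.52, CCDC190 by 3.77, CST2 by 3.63, ATOH8 by 3.61, ACTA2 by 1.08, VCL by 0.64 and MRTFB by 0.27. It was more negative for SPNS2 by -3.89, FOSB by -3.68, DUSP13 by -2.89, RNF223 by -2.87, ADM2 by -2.59 and TNC by -1.64. Levels behind some of these were 7.03 ± 1.42 CPM of ATOH8 in 2D control, 0.167 ± 0.0876 in 2D WT, 34.9 ± 4.83 in 3D control and 10.8 ± 0.813 in 3D WT, and for FOSB 0.607 ± 0.15, 5.57 ± 0.207, 2.39 ± 0.374 and 1.69 ± 0.243. List medians were more positive for cytoskeletal MRTF/SRF targets (0.40), mitosis genes (0.42), interferon response genes (0.22) and replication-dependent histone genes (0.81), with adjusted p = 7.33e-06, 6.97e-06, 0.00174 and 0.00171 (0.395, 0.679, 0.0380 and 0.731 with an estimated correlation). They were more negative for immediate early genes (-1.06, and -0.46 on log2(TPM + 1)), cholesterol synthesis genes (-0.30), ATF4 and unfolded protein response genes (-0.83) and p53 targets (-0.19), with adjusted p = 1.68e-04, 8.45e-07, 2.21e-19 and 0.0280 (0.0719, 0.107, 4.69e-04 and 0.413 with an estimated correlation). Leaving out 1 library ended the calls of several of these genes. These were ACTA2 (any of the 12 libraries compared, adjusted p = 0.0505 to 0.123), TRAC (all but 2D control 2 and 3D WT 2, 0.0504 to 0.0799), RNF223 (all but 2D control 1, 2D WT 2 and 3D control 2, 0.0516 to 0.0763) and ATOH8 (any 2D WT library, 0.0550 to 0.0718). They were also FLT1 (any 3D control library or 3D WT 1, 0.0505 to 0.0663), CST2 (2D control 1, 2D WT 2 or 2D WT 3, 0.0522 to 0.0609) and MRTFB (2D control 3, 2D WT 1, 3D control 1 or 3D WT 3, 0.0521 to 0.10). On log2(TPM + 1) MRTFB stood at -0.19, FLT1 at -0.0011, SPNS2 at -0.83, TRAC at 0.72 and ATOH8 at 1.02, none of them called (adjusted p = 0.759, 1, 0.159, 0.15 and 0.306). TRAC and FLT1 were also not called with replicate as a block (adjusted p = 0.0624 and 0.0593).

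The dSAP effect differed between cultures for 350 genes (206, 225 and 217 without 2D dSAP 3, 3D dSAP 2 and 3D dSAP 3). It was more positive in 3D for ATAT1 by 10.38, WNT3 by 3.37, CCDC190 by 3.18, DMBT1 by 2.64, SEC14L6 by 2.02 and VCL by 0.48. ATAT1, an MHC-region gene, had 5.15 ± 1.35 CPM in 2D control, 0 in 2D dSAP, 2.24 ± 2.52 in 3D control and 4.06 ± 1.75 in 3D dSAP. The effect was more negative for FOSB by -3.24, PCLO by -2.09, SERPINE2 by -1.69, TNC by -1.62 and COL17A1 by -1.52. List medians differed for cytoskeletal MRTF/SRF targets (0.31), interferon response genes (0.24), cholesterol synthesis genes (-0.31), ATF4 and unfolded protein response genes (-0.40) and leukocyte markers (0.29; 1 of 3 members higher and 0 lower), with adjusted p = 6.34e-04, 1.38e-07, 2.41e-08, 6.23e-16 and 0.0373. An estimated correlation gave adjusted p = 0.518, 0.00105, 0.0689, 8.21e-04 and 0.395. The leukocyte call was lost without any of 10 of the 12 libraries compared (all but 3D control 2 and 3D control 3), with adjusted p from 0.0952 to 0.324, or without the library labelled 3D dSRF 1 (0.315). The ATAT1 call was lost without the same libraries (adjusted p = 0.0565 to 0.0926) and that of CCDC190 without any of the 12 (adjusted p = 0.0509 to 0.115). With replicate as a block both were lost (adjusted p = 0.0757 and 0.0576), and log2(TPM + 1) ended the calls of CCDC190, SEC14L6 and SERPINE2 (adjusted p = 0.0892, 0.0746 and 0.102).

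The dSRF effect differed between cultures for 4379 genes (6680 without the library labelled 3D dSRF 1, 2642 with only the libraries compared). It was more positive in 3D for DMBT1 by 6.03 (6.37 without it), DEFB103B by 5.35 (5.11 without it), SOST by 5.23 (5.58 without it), NPPB by 5.04 (4.11 without it) and KISS1 by 4.90 (2.58 without it), and for CCN1 by 3.18 (2.60 without it), CCN2 by 2.24 (1.08 without it) and VCL by 0.71 (0.75 without it). It was more negative for CELF6 by -6.24 (-5.90 without it), CDH16 by -5.25 (-4.70 without it), CXCL10 by -5.11 (-5.61 without it), PAPPA2 by -4.77 (-4.30 without it) and IL36G by -4.34 (-4.04 without it), and for TNC by -3.22 (-3.64 without it), TAGLN by -2.97 (-4.17 without it) and MRTFB by -0.38 (-0.41 without it). The CELF6 call was lost without that library (adjusted p = 0.0634) or any other but 3D control 2 and 3D dSRF 2 (0.0548 to 0.117), and with replicate as a block (0.0693). On log2(TPM + 1) the calls of CELF6, PAPPA2 and IL36G were lost (adjusted p = 0.154, 0.357 and 0.0624), that of IL36G also with DESeq2 (0.0537). The PAPPA2 call was lost without any 2D control or 2D dSRF library, 3D control 1 or 3D control 2 (adjusted p = 0.0545 to 0.0868). That of CDH16 was lost without 2D control 1, 3D control 1 or 3D control 2 (0.0502 to 0.10) and that of IL36G without 2D control 1, 2D control 3 or 3D control 1 (0.0508 to 0.0552). NPPB moved to 7.71 without 3D control 2. List medians were more positive for cytoskeletal MRTF/SRF targets (0.30), YAP/TEAD targets (0.69), epithelial markers (0.96), cholesterol synthesis genes (0.15) and fatty acid genes (0.35), with adjusted p = 0.00289, 4.65e-06, 5.98e-05, 0.00581 and 0.00198 (0.572, 0.495, 0.334, 0.413 and 0.0719 with an estimated correlation). They were more negative for mitosis genes (-0.59), DNA replication genes (-0.93), NF-kB feedback genes (-0.55) and mitochondrial genome genes (-0.77), with adjusted p = 1.39e-04, 3.33e-09, 2.28e-04 and 0.0258 (0.740, 0.532, 0.199 and 0.769 with an estimated correlation). Without that library the medians moved to 0.18 for cytoskeletal targets, 0.32 for YAP/TEAD targets, 0.30 for cholesterol synthesis, -1.17 for mitosis and -1.45 for DNA replication genes. The mitochondrial call was lost without the library labelled 3D dSRF 1 (adjusted p = 0.235), 2D control 3 (0.145), 2D dSRF 1 (0.0771), 2D dSRF 2 (0.050) or 3D control 3 (0.0681).

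In each interaction, 5 of 40 random splits drawn from 200 distinct ones, the real one included, gave as many called genes, so this count does not exclude chance. The real values were 1376, 350 and 4379 for WT, dSAP and dSRF, and the highest of the other splits 3667, 2733 and 9018. Of the 8 splits that kept the real grouping in one culture, 4 gave as many, whereas the 31 that mixed both cultures gave at most 0, 1 and 0, so the large values point to a structure of the samples, the difference between lines itself.

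For the 13 comparisons of 2 groups, the 10 splits of 6 libraries, of which 1 (the real one) gave as many called genes in each, are too few for a share under 0.05. In 2D the real counts were 5891 for WT, 4937 for dSAP and 9885 for dSRF against control, 1919 for dSAP and 9594 for dSRF against WT and 9739 for dSAP against dSRF. The highest of the other splits gave 0, 1, 0, 1, 0 and 0. In 3D they were 5244, 4435, 9948, 1810, 9869 and 9699 in the same order, and the highest of the others gave 0, 0, 3214, 0, 3069 and 2906. For control in 3D against 2D the real count was 7097 and the highest other 0.

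The library labelled 3D dSRF 1 lay apart from the others of its group, with MRTFA at 0.137 of their mean. Mixture with cells of another line is argued against: it would lower the 26 genes read only in dSRF by a common factor, and their median ratio to the other libraries (0.136) was near that of MRTFA, but the 90th percentile of these ratios was 14.6 times the 10th, against 1.46 between those other libraries. A 2D culture under a 3D label could account for its place on an axis of 1395 culture genes (0 at the 2D libraries of the line), 0.0152, where the others lay at 0.299 and 0.282, but not for MRTFA at 664 CPM beside 3237 ± 107 in 2D dSRF. Lower induction of the construct could account for its smaller changes in dSRF genes, with a slope of 0.622 ± 0.00867 on the other libraries over 3389 genes (0.981 between those), but is argued against for the culture genes, where the library lay 0.267 below the lower of the others. A 2D culture together with lower induction, a 2D culture together with cells of another line, and a handling difference stay open. No biological explanation was tested, since the labels give no difference within the group.

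The dSRF line differed from control in more genes than the WT and dSAP lines. A higher level of the construct is argued against, since mean MRTFA in dSRF was 0.354 of that in dSAP in 2D and 0.329 in 3D (without the library labelled 3D dSRF 1, dSRF lay 1.12 below dSAP and 0.10 above WT, adjusted p = 0.0596). Another cell line with an intact 9p21 region, which MDA-MB-231 is known to lack, is argued against by at most 0.0493 CPM of CDKN2A, CDKN2B and MTAP in any dSRF library, and copy number differences as the whole cause by the 2.44% of the variance that windows of 10 Mb held beyond chance (3.83% in 2D WT). Of 277 windows, 6 in 2D and 8 in 3D dSRF had a median beyond 0.5 (largest -1.10 and -1.07), against 0 in 2D WT and 2D dSAP, so regional differences of the line stay open. With 1 line per construct, the effect of the dSRF protein and the history of that line cannot be told apart.

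Genes of the MHC region with very large changes between lines, TRIM26, ATAT1, BAG6, C4B and PRRC2A among them, are the third pattern. Reads split between alternative copies of the region could account for them: the median dispersion of its 90 tested genes was 5.06 times (95% interval 2.22 to 8.15) that of other genes of like abundance. HLA-DRB1, which also fell, had a ratio of 0.776 (TRIM26 72.1), so this spread is not a reason to doubt it. A biological change of these genes stays open and was not tested.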

How the results depend on the processing

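The fit without the library labelled 3D dSRF 1, the restriction to genes with a symbol outside the MHC region and the alternatives for the overlaps were chosen after seeing the data. All others were fixed before. Every count of called genes kept within 1.5 times its value under RLE size factors, without a filter on low counts, with the replicate number as a block and for genes with a symbol outside the MHC region. Of 36 correlations between same-numbered libraries, 1 was above 0.1 (range -0.123 to 0.108), which leaves pairing in some genes open. The block called 167 lists rather than 165 and lost glycolysis (adjusted p = 0.0651) and ribosomal protein genes (adjusted p = 0.0782) in control 3D against 2D and leukocyte markers in the dSAP interaction (adjusted p = 0.0589). It also ended 8 calls of single genes, given beside them. RLE size factors lost 1 list call. On log2(TPM + 1) the medians of 34 of the 165 called lists differed by over 1.5 times, and none changed sign. Of the 165 list calls, 14 held with an estimated correlation, and no called list had a median opposing its test. Small changes can be missed: among 100 genes changed by 1.5-fold on simulated data, 55 were recovered in 2D WT against control and 47 in the WT interaction, and of 100 changed by 2-fold 78 and 74. In the following, where no cause is given, the cause was not tested.

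Groups taken from the genotype field, which mix the lines, gave 0 called genes in 15 comparisons and 0 shared genes in all 12 overlaps, and 23 genes for control in 3D against 2D. With only the libraries compared in the fit, the counts were 4288 for dSAP against WT in 2D, 4607 in 3D, and 3463, 1400 and 2642 for the WT, dSAP and dSRF interactions. Without the library labelled 3D dSRF 1 they were 4220 and 4149 for dSAP against WT in 2D and 3D, 6715 for 3D dSAP against control, and 3636 and 1738 for the WT and dSAP interactions. limma-trend on log2(TPM + 1) gave 909 and 200 for the WT and dSAP interactions, 869 genes lower in both 2D dSAP and dSRF and 1017 higher in both 3D WT and dSRF. DESeq2 gave 598 for the dSAP interaction.

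Leaving out 1 library of the groups compared at a time gave 4982 to 5209 called genes for WT, 3899 to 4289 for dSAP and 9223 to 9362 for dSRF against control in 2D, and 4387 to 4553, 3517 to 3800 and 9418 to 11098 in 3D. For dSAP against WT it gave 1171 to 1525 in 2D and 1186 to 1304 in 3D, for dSRF against WT 8939 to 9124 and 9175 to 11107, for dSAP against dSRF 9087 to 9271 and 9052 to 10969 and for control in 3D against 2D 5979 to 6446. The interactions gave 973 to 1213 (WT), 206 to 295 (dSAP) and 3679 to 6680 (dSRF), the list tests 163 to 198 calls, and the genes lower in both 3D dSAP and dSRF 859 to 1915. The highest values of the comparisons with 3D dSRF came without the library labelled 3D dSRF 1. Fits with fewer libraries otherwise have less power. Signs of some single genes changed. Without 1 library, MRTFA in 3D dSRF against WT ran from -0.72 to 0.10, the latter without the library labelled 3D dSRF 1 (adjusted p = 0.0596). In 2D dSRF against control, CNN1 ran from -0.024 to 1.21 and MYL9 from -0.20 to 0.22. With log2(TPM + 1) and with log2(TPM + 0.1), VCL in 2D dSRF against control was 0.029, the MRTFA dSRF interaction -0.19 and the MRTFB WT interaction -0.19, and FLT1 in the WT interaction was -0.0011 with log2(TPM + 1). None of these values was called, whereas the reported FLT1 and MRTFB interactions were.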

Other observations

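The genes named here were chosen after their values were seen, and no hypothesis was tested on them. Values are CPM (mean ± SD, n = 3) in control, WT, dSAP and dSRF. ID1, which BMP signalling induces, held 87.1 ± 4.74, 5.43 ± 0.861, 16.5 ± 2.13 and 12.1 ± 0.431 in 2D and 207 ± 11.5, 100.4 ± 7.99, 159 ± 8.76 and 41.2 ± 30.6 in 3D. CIITA, the main activator of MHC class II genes, held 28.5 ± 1.77, 3.12 ± 0.620, 4.68 ± 0.611 and 8.29 ± 0.531 in 2D and 62.0 ± 4.59, 18.2 ± 1.67, 23.1 ± 1.01 and 5.66 ± 1.64 in 3D.

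The luminal transcription factor FOXA1 held 0 ± 0, 0.0645 ± 0.00499, 0.0216 ± 0.0374 and 13.5 ± 1.08 in 2D and 0.0167 ± 0.0290, 0.0786 ± 0.0724, 0.0853 ± 0.0570 and 12.8 ± 10.4 in 3D, and MKI67, a marker of cycling cells, 607 ± 36.8, 377 ± 15.6, 416 ± 19.4 and 165 ± 9.60 in 2D and 675 ± 36.7, 562 ± 26.7, 477 ± 11.6 and 104 ± 79.2 in 3D. The stress gene DDIT3 held 6.70 ± 0.714, 16.2 ± 0.795, 11.2 ± 0.673 and 12.9 ± 0.0626 in 2D and 12.5 ± 0.247, 6.47 ± 0.186, 7.80 ± 0.485 and 17.9 ± 5.40 in 3D. Without the library labelled 3D dSRF 1 the 3D dSRF means were 58.6 for ID1, 4.72 for CIITA, 18.8 for FOXA1, 58.5 for MKI67 and 14.7 for DDIT3. No test was called for the lists of TGF-beta response genes (lowest adjusted p = 0.233), endothelial markers (0.244), luminal breast line markers (0.135) and matrix proteases and inhibitors (0.0948).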
